A study of Mus musculus with 271 samples.

How the data were processed

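RNA was sequenced from individual CD4 T cells of the spleens of Apoe-/- mice, a strain that lacks apolipoprotein E and develops atherosclerosis. The cells were sorted for the surface proteins CD4, CD73, PD1, CD25 and CCR5 and captured on Fluidigm C1 chips, per the labels' protocols. The mice were 40 weeks old, and each of the 6 chip preparations pooled 4 to 5 spleens. Libraries were made with SMARTer and Nextera XT reagents and sequenced as 50 bp reads, 48 libraries in each of 6 lanes. TopHat2 and R 3.0.3 are named in the submitters' processing notes, with the mouse build mm10. The program that made the expression values is not given in the sources used here.

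The authors deposited a table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of each library) and a file that places cells in the classes Th1, Treg or Th1/Treg. How the cells were classed is not given in the sources used here, though the design, fixed before the data were examined, assumed that expression was used. If the classes were set from expression of some of the genes tested, the differences of those genes follow in part from the classing. The FPKM table has 267 columns, of which 263 matched a sample by title. The other 4 matched no sample and were not used, and 8 of the 271 samples had no column. Of the 20145 rows, 157 repeat a symbol, and the highest value of the copies was taken in each cell, which left 19988 symbols. FPKM values are not counts, and values as low as 8.5e-286 show that whole reads cannot be recovered from them, so the read depth of each cell is unknown. The number of genes above 1 FPKM is given in its place. A value of 0 can be a transcript that was not captured, so a gene is described as listed above 1 FPKM in a number of cells.

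Of the 263 cells, 175 had a class and 88 had none. The column of 1 Th1 cell of chip 7 has its values displaced against the gene names, by 15 positions at the top of the table and by 101 between lines 18001 and 19500. Its correlation with the mean of the other cells was 0.00457, against 0.235 for the lowest other classed cell, and Actb, B2m and Eef1a1 stood at 0. It was left out. A pair of Th1 cells of chip 7 correlated at r = 0.987 and another pair, 1 Th1/Treg cell and 1 cell without a class, at r = 0.984. No other pair of cells went above 0.579. The Th1 pair was averaged and counted as 1 cell. This left 81 Th1, 71 Th1/Treg and 21 Treg cells. No doublet caller was run, since the depth is unknown and the cells were loaded on chips.

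Cells of a chip are not independent replicates, so the chip, a pool of spleens, was the replicate. For each chip and class with at least 2 cells, the mean of log2(FPKM + 1) was taken over the cells. All differences are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. Genes above 1 FPKM in at least 10% of the classed cells were tested, which left 3381 genes. The means were fitted with limma 3.58.1 in R 4.3.3, with a term for each class, the chip as a block, weights equal to the number of cells, and moderated variances with a trend and robust settings. Tests were two-sided, and the Benjamini-Hochberg adjusted p threshold was 0.05. The residual degrees of freedom were 8. The chip numbers come from the sample titles, and cells of the same number share a chip and a pool of spleens, which is why the chip was a block. A first fit used limma's approximate standard errors for differences under a matrix of weights. These changed with the chip taken as baseline, so after its calls had been seen it was replaced by the fit with exact weighted standard errors. The first fit is kept among the alternatives.

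The design, the tests, the gene lists and most alternatives were fixed before the data were examined. The exceptions, chosen after, were the exact standard errors of the fit, the count of Treg list genes per cell, the counts of other-cell markers by class and chip, and the tests and alternatives named as such in the closing section. The rule for named genes took, for each comparison, the 10 largest rises and 10 largest falls among genes past the threshold that changed the same way in every chip holding both classes. It added up to 4 genes of each list that passed, and where fewer than 5 genes passed, the 5 lowest p in each direction. Cd4, Nt5e, Pdcd1, Il2ra, Ccr5, Foxp3, Tbx21, Ifng and Cxcr3 were always named. Genes above 1 FPKM in at least 95% of a class and at most 5% of another were to be left out as class-defining, and 0 were found.

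The lists with at least 5 tested genes, 21 in number, were tested with camera and an estimated correlation between genes. A preset correlation of 0.01 and fry were alternatives. The lists covered Treg, Th1 and Tfh genes, naive and central memory genes, activation and costimulation, co-inhibition and exhaustion, T cell receptor, STAT5 and interleukin 2, TGF-beta, and PI3K with AKT, mTOR and FOXO signalling. They also covered chemokine receptors and adhesion, cytotoxic granules, interferon response, apoptosis, cell cycle, glycolysis, oxidative phosphorylation, cholesterol and lipid handling, dissociation stress, and markers of B cells and of myeloid cells. The lists of Th17, Th2, sort gate, CD8 T and NK, and red cell genes had too few tested genes for the test. No ribosomal protein gene of the fixed list had a row in the table. Some genes are on more than 1 list, so the lists are not independent. Tnfrsf4 and Tnfrsf9 are on the Treg list and the activation list, and Tigit is on the Treg list and the co-inhibition list.

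Genes detected per cell were compared by an exact two-sided sign-flip test over chips. The position of Th1/Treg cells between Th1 and Treg was measured in each chip along 200 genes chosen in the other chips, with 0 at the Th1 mean and 1 at the Treg mean. Shares of cells are given with exact Clopper-Pearson 95% intervals, which cover counting error only.

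The fit was tested on simulated data made by shuffling classes within chips and adding known shifts to 200 of the 3381 genes in each of 10 draws. A shift was added to the chip means of a class, by the same amount in every chip. Changes that vary between chips or between cells were not simulated, so the rates below do not cover them. A shift of 4 was recovered in 96.1% of the changed genes for Treg minus Th1, a shift of 2 in 41.3% and a shift of 1 in 4.93%. For Th1/Treg minus Th1 these were 99.8%, 88.8% and 24.9%, and for Th1/Treg minus Treg 95.2%, 39.4% and 2.69%. False calls made up 7.00%, 4.37% and 5.89% of the calls in the same order of comparisons. Lists were simulated for Treg minus Th1 alone, where a list shifted by 2 was called in 10 of 10 draws, with 1 call of another list and 0 without a shift. Without any shift, 0 genes were called for Treg minus Th1 and for Th1/Treg minus Th1, and 4 genes, all in 1 of the 10 draws, for Th1/Treg minus Treg.

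Gene positions are from GENCODE M21, on GRCm38, the assembly that mm10 names. All 41 genes looked up were found, by symbol or by a synonym in the RefSeq gene table. Alternatives covered the pseudocount, the filter, the summary per chip, the block, the weights, the minimum number of cells, the scaling, the cells kept and each chip left out. Figures were drawn with matplotlib 3.10.9, and Fisher's exact test was run in scipy 1.17.1.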

Results

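The data are FPKM profiles of individual T cells sorted from the spleens of 40-week-old Apoe-/- mice on CD4, CD73, PD1, CD25 and CCR5. The stated purpose was to compare Th1, Treg and Th1/Treg cells isolated together. Th1 cells are helper cells that make interferon gamma, and Treg cells are regulatory cells that restrain immune responses. The classed cells were 81 Th1, 71 Th1/Treg and 21 Treg cells. Th1 and Th1/Treg cells came from all 6 chips, and Treg cells entered the tests from 4 chips, with 5, 10, 2 and 3 cells in chips 4, 5, 6 and 7. The median number of genes above 1 FPKM was 971 in Th1, 1086 in Th1/Treg and 1377 in Treg cells. Single classed cells ranged from 322 to 3180 genes. By chip, the median over all cells ran from 643 in chip 2 to 1375 in chip 5. Read depth is unknown, and the summed FPKM of a cell ranged from 795 to 10059645 with a median of 262494.

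The genes behind the sort were seldom listed above 1 FPKM. Ccr5, a chemokine receptor, was above 1 FPKM in 3 of the classed cells, and Pdcd1, which encodes PD1, in 7. Il2ra, which encodes CD25, was above 1 FPKM in 60 cells, Cd4 in 50 and Nt5e, which encodes CD73, in 24. Tbx21, the master transcription factor of Th1 cells, was above 1 FPKM in 3 cells, in 2 of 81 Th1, 0 of 21 Treg and 1 of 71 Th1/Treg cells. The chemokine receptor gene Cxcr3 was above it in 12, in 4 of 81 Th1, 5 of 21 Treg and 3 of 71 Th1/Treg cells. Neither gene was in enough cells to be tested. These shares describe capture of transcripts at an unknown depth and say nothing of the surface proteins.

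Treg cells were first compared with Th1 cells. The differences are estimates within chips, weighted by cells, and so differ from those between plain means over chips. Tnfrsf9 (4-1BB), a receptor of the tumour necrosis factor family, rose by 6.72 ± 1.10 on the log2 scale (SE, adjusted p = 0.00283). Its plain mean over chips was 0.58 ± 1.07 in Th1 cells (SD, n = 6 chips) and 8.18 ± 0.96 in Treg cells (SD, n = 4 chips). It was above 1 FPKM in 21 of 21 Treg and 15 of 81 Th1 cells. Tnfrsf4 (OX40), of the same family, rose by 6.65 ± 1.04 (SE, adjusted p = 0.00261), and Tnfrsf18 (GITR), also of that family, by 5.40 ± 0.84 (SE, adjusted p = 0.00261). Folr4, the folate receptor family gene now named Izumo1r, rose by 6.31 ± 1.01 (SE, adjusted p = 0.00261).

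Further rises took in an inhibitory receptor, a transcription factor and granule genes. Tigit, an inhibitory receptor, was higher by 4.94 ± 0.90 (SE) and was above 1 FPKM in 21 of 21 Treg and 34 of 81 Th1 cells. Ikzf2, the transcription factor Helios, was higher by 4.41 ± 0.75 (SE), and Capg, an actin-capping protein, by 5.42 ± 1.01 (SE). Srgn, the granule proteoglycan serglycin, was higher by 4.72 ± 0.94 (SE), Pglyrp1, a peptidoglycan recognition protein, by 4.66 ± 0.88 (SE), and Glrx, glutaredoxin, by 3.70 ± 0.81 (SE). Their adjusted p ran from 0.00384 for Ikzf2 to 0.0316 for Glrx. All these genes were higher in 4 of 4 chips.

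In all, limma called 17 of 3381 genes higher in Treg cells and 0 lower. With at least 4 cells per chip and class 0 were called, at a lowest limma adjusted p of 0.0688, and without a filter on low values 0. At an unadjusted p under 0.05 there were 381 higher and 52 lower. Cd3g, a chain of the T cell receptor complex, rose by 4.28 ± 0.98 (SE, adjusted p = 0.0455) and was higher in 3 of 4 chips. Nt5e rose by 2.33 ± 0.49 (SE, adjusted p = 0.0237) in 4 of 4 chips. The remaining 5 called genes, named after their values were seen, were Serinc3, Igflr1, Tnip1, Serpinb6a and Fnip1, with differences from 3.60 to 1.77. Foxp3, the master transcription factor of Treg cells, differed by 1.84 ± 0.55 (SE, adjusted p = 0.137) and did not pass. It was above 1 FPKM in 8 of 21 Treg and 5 of 81 Th1 cells. Il2ra differed by 0.02 ± 0.70 (SE, adjusted p = 0.997), Cd4 by 1.62 ± 0.75 (SE, adjusted p = 0.355) and Ifng, the gene of interferon gamma, by -0.36 ± 0.43 (SE, adjusted p = 0.794).

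**Figure D1:**
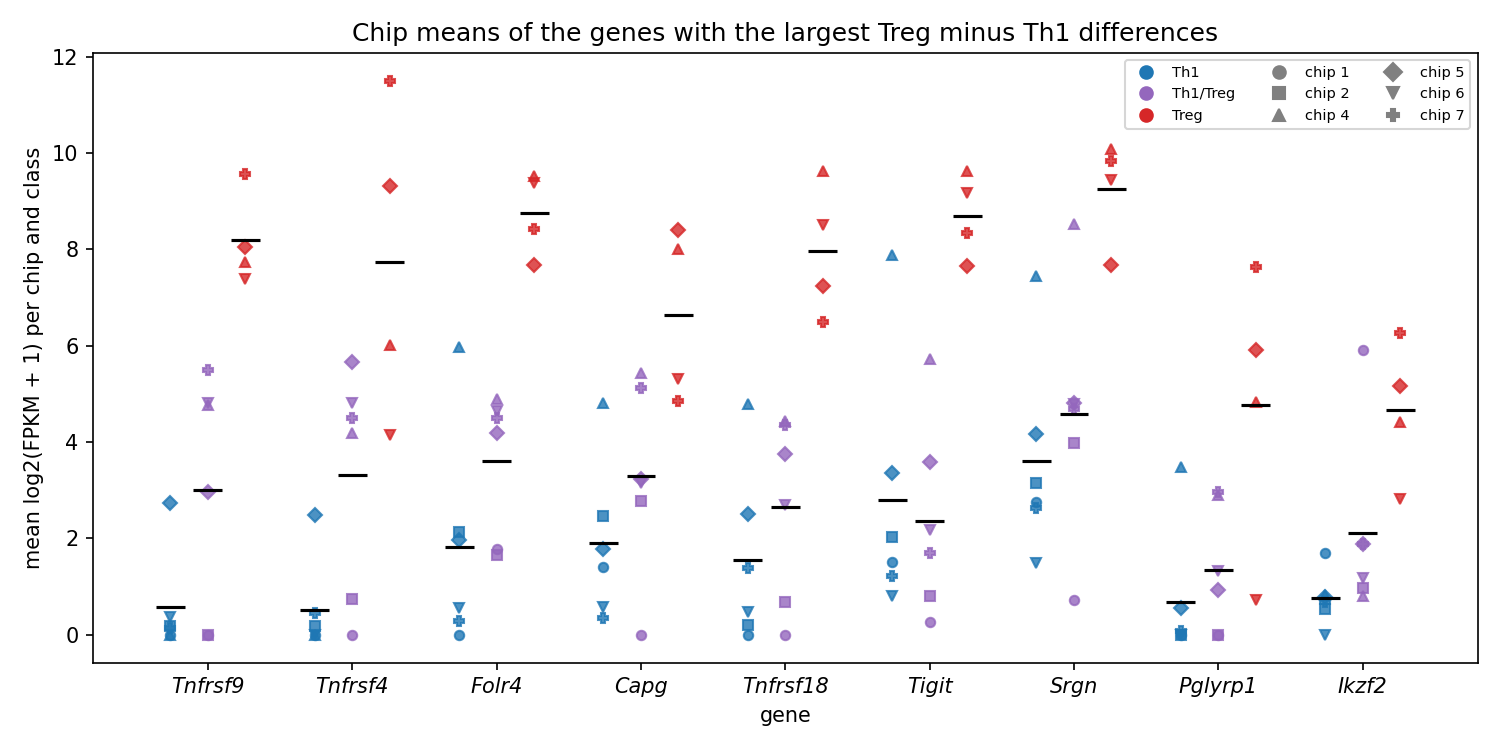
Each point is the mean log2(FPKM + 1) of the cells of a class on a chip, for the 9 genes with the largest Treg minus Th1 differences, with the chip shown by the marker and the class by colour, and black bars are means over chips. The Treg mean of Tnfrsf9 is 8.18, against 0.58 in Th1 and 3.01 in Th1/Treg cells.

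The list of Treg identity and suppression genes rose as a group in Treg cells (camera adjusted p = 0.00597), with 22 of 23 tested members higher. Of these, 8 passed over all genes and 17 when adjusted over the list alone. Among those that passed over the list alone, Ctla4, an inhibitory receptor, differed by 3.60 ± 0.93 (SE) and the cytokine gene Il10 by 2.13 ± 0.62 (SE), both higher in 4 of 4 chips. Icos, a costimulatory receptor, differed by 2.46 ± 0.62 (SE) and was higher in 3 of 4. The naive and central memory list fell (camera adjusted p = 0.0268), with 13 of 15 members lower. Klf2, a transcription factor of resting T cells, was the member that passed when adjusted over the list alone, by -1.93 ± 0.54 (SE) and lower in 4 of 4 chips, and 0 members passed over all genes. The naive and central memory call was lost without any of the 6 chips except chip 1, with an adjusted p of up to 0.116. It was also lost with the other-cell markers as a covariate (adjusted p = 0.217), with the log taken of the mean FPKM (adjusted p = 0.0899) and without the chip as a block (adjusted p = 0.0756). The Th1 identity and effector list was not called against other genes (camera adjusted p = 0.952), with 9 of 14 members higher. Its unadjusted mixed p in fry, which tests for change in either direction and not against other genes, was 0.000254. Other lists had a lower mixed p in fry, among them T cell receptor genes (8.71e-06) and co-inhibition (1.47e-05), so this value does not set the Th1 list apart. The Th1 list members that passed when adjusted over the list alone were Bhlhe40, Ifngr1 and Stat1, named after their values were seen. They were higher by 3.06 ± 0.80, 2.48 ± 0.86 and 2.34 ± 0.84 (SE).

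Markers of other cells were counted beside this comparison. At least 2 myeloid or dendritic markers were above 1 FPKM in 16 of 21 Treg and 26 of 81 Th1 cells, and at least 2 B cell markers in 14 of 21 and 18 of 81. The B cell list includes Cd74 and the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1, which are not particular to B cells. Within chips, Treg cells had 0.989 ± 0.722 more myeloid markers per cell (SD, n = 4 chips, exact sign-flip p = 0.25, smallest possible 0.125) and 0.328 ± 0.501 more B cell markers (SD, n = 4 chips, exact sign-flip p = 0.5). The myeloid number was higher in 3 of 4 chips and the B cell number in 2 of 4. The B cell counts over all cells follow the chips, since 84% of the classed cells of chip 5 and 75% of those of chip 4 had at least 2 such markers. With the number of such markers as a covariate, 0 genes were called, and the Treg list had an adjusted p of 0.115. The 17 genes were all still higher, by a median of 4.24 ± 1.46 against 4.41 ± 0.84 (SE), so the calls ended with a larger standard error. The median difference of the Treg list fell from 2.33 to 1.89. Without chip 5, which holds 10 Treg cells, 0 genes were called and the Treg list had an adjusted p of 0.0657. The 12 genes named by the rule were all higher, by a median of 5.50 against 4.83 with every chip. That direction follows largely from the rule, which favoured genes that were higher in every chip. Without chip 2 or chip 7, 11 and 9 genes were called. With the log taken of the mean FPKM of each chip and class, 1 gene was called, and the median difference of all genes moved from 0.20 to -0.23.

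Th1/Treg cells were next compared with Treg cells. Tigit was lower by 4.90 on the log2 scale, at -4.90 ± 0.86 (SE, adjusted p = 0.0282), and lower in 4 of 4 chips. It was above 1 FPKM in 34 of 71 Th1/Treg and 21 of 21 Treg cells. The plain mean over chips was 2.37 ± 2.00 in Th1/Treg cells (SD, n = 6 chips) and 8.70 ± 0.87 in Treg cells (SD, n = 4 chips). This was the called gene of the 3381 tested with limma, with 29 higher and 347 lower at an unadjusted p under 0.05. Without chip 2, 4 or 5, 0 genes were called, and without chip 6 or 7 there were 4 and 7. Tigit stayed lower under each of 22 alternatives, from -6.14 to -3.74, but did not pass in 12 of them. Among these were a pseudocount of 0.1 (adjusted p = 0.0515), no block (adjusted p = 0.0666), at least 4 cells per chip and class (adjusted p = 0.139), the other-cell markers as a covariate (adjusted p = 0.681) and the log of the mean FPKM (adjusted p = 0.956).

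The Treg identity and suppression list fell in Th1/Treg cells relative to Treg cells (camera adjusted p = 0.0333), with 21 of 23 members lower. Of these, 1 passed over all genes and 12 when adjusted over the list alone. Tnfrsf18 differed by -3.92 ± 0.80 (SE, adjusted p = 0.0671) and Ikzf2 by -3.28 ± 0.72 (SE, adjusted p = 0.0671), short of the threshold over all genes. Nt5e differed by -1.96 ± 0.46 (SE, adjusted p = 0.0757) and Foxp3 by -1.78 ± 0.53 (SE, adjusted p = 0.136). Cep57, a centrosome protein, and Serpinb6a, a protease inhibitor, had the other low p among genes that were lower, at -1.95 ± 0.41 and -2.43 ± 0.52 (SE, adjusted p = 0.0671 each).

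No gene was called higher in Th1/Treg than in Treg cells. The lowest p in that direction belonged to Xrcc2, Mrpl23, Ugcg, Inpp5k and Bin3, which did not pass, with adjusted p from 0.255 to 0.309. Ifng differed by 0.88 ± 0.41 (SE, adjusted p = 0.437), and was above 1 FPKM in 13 of 71 Th1/Treg cells, 5 of 81 Th1 cells and 1 of 21 Treg cells. Il2ra differed by 0.18 ± 0.67 (SE, adjusted p = 0.968) and Cd4 by -1.31 ± 0.72 (SE, adjusted p = 0.518). The Th1 list was not called against other genes (camera adjusted p = 0.731). Its unadjusted mixed p in fry was 0.000594, while the Treg list (6.53e-07) and T cell receptor genes (8.42e-05) had lower ones. In the Th1 list 1 member passed lower when adjusted over the list alone, Bhlhe40 at -2.50 ± 0.76 (SE), named after its value was seen. Th1/Treg cells had fewer genes detected than Treg cells, at -198.8 ± 59.7 (SD, n = 4 chips, exact sign-flip p = 0.125, the smallest these chips can give), and were lower in each of the 4 chips. They also had fewer myeloid markers per cell, at -1.28 ± 0.642 (SD, n = 4 chips, exact sign-flip p = 0.125). The list call was lost without chip 4, 5, 6 or 7, with an adjusted p of up to 0.227. It was also lost with the other-cell markers as a covariate (adjusted p = 0.469), with the log taken of the mean FPKM (adjusted p = 0.55) and with each cell scaled to the same sum (adjusted p = 0.0509). With the number of genes detected as a covariate, the list had an adjusted p of 0.0722 and 0 genes were called, while Tigit stayed at -4.46 against -4.90 (adjusted p = 0.303).

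Th1/Treg cells were last compared with Th1 cells. Il2rg, the common gamma chain shared by receptors of interleukin 2 and related cytokines, rose by 3.21 ± 0.52 (SE, adjusted p = 0.00976) and was higher in 5 of 6 chips. Its plain mean over chips was 6.34 ± 0.90 in Th1/Treg and 3.72 ± 2.54 in Th1 cells (SD, n = 6 chips each), and it was above 1 FPKM in 65 of 71 and 45 of 81 cells. Il2rg stayed higher under each of 23 alternatives, by 2.10 to 4.16, but did not pass in 11 of them. Among these were equal weights (2.62, adjusted p = 0.999), genes detected as a covariate (3.05, adjusted p = 0.0534), the log of the mean FPKM (2.10, adjusted p = 0.168) and the fit without cells holding other-cell markers or the most genes (3.53, adjusted p = 0.993). Of 3381 genes, limma called 1 higher and 0 lower, with 3.25% higher and 3.46% lower at an unadjusted p under 0.05.

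The Treg identity and suppression list was higher in Th1/Treg than in Th1 cells (camera adjusted p = 0.0436), with 22 of 23 members higher. Of these, 0 passed over all genes and 6 when adjusted over the list alone. The largest of the 6 was Tnfrsf4, at 2.92 ± 0.65 (SE, adjusted p = 0.273 over all genes). Ctla4 differed by 2.12 ± 0.58 (SE, adjusted p = 0.414), Folr4 by 2.21 ± 0.63 (SE) and Tnfrsf9 by 2.20 ± 0.69 (SE). Tnfrsf4 and Tnfrsf9 are also on the activation and costimulation list, so their rise is not particular to Treg identity. Tigit differed by 0.04 ± 0.56 (SE, adjusted p = 0.991) and Foxp3 by 0.06 ± 0.34 (SE, adjusted p = 0.979).

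Other genes with low p that did not pass were Ly6a, a surface antigen of activated T cells, at 2.23 ± 0.59 (SE), and Vps54 at 1.62 ± 0.43 (SE). Among genes that were lower, Eif1a, Srrt, Fam105a, Pydc3 and Fam120b had the lowest p, with adjusted p from 0.370 to 0.414. Ifng differed by 0.51 ± 0.27 (SE, adjusted p = 0.781), Nt5e by 0.37 ± 0.30 (SE, adjusted p = 0.898), Il2ra by 0.20 ± 0.44 (SE, adjusted p = 0.962) and Cd4 by 0.31 ± 0.47 (SE, adjusted p = 0.946). The Th1 list was not called against other genes (camera adjusted p = 0.546). Its unadjusted mixed p in fry was 0.00258, while the STAT5 and interleukin 2 list (2.82e-07) and the Treg list (0.000152) had lower ones. In the Th1 list 1 member passed higher when adjusted over the list alone, Ifngr1 at 1.79 ± 0.54 (SE), named after its value was seen. The gene count also depended on single chips, since 0 genes passed without chip 2, 5, 6 or 7, and 2 passed without chip 1. The Treg list call was lost without any of the 6 chips except chip 2, with an adjusted p of up to 0.210. It was also lost with genes detected as a covariate (adjusted p = 0.269), with the log taken of the mean FPKM (adjusted p = 0.155) and with each cell scaled to the same sum (adjusted p = 0.0603).

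**Figure D2:**
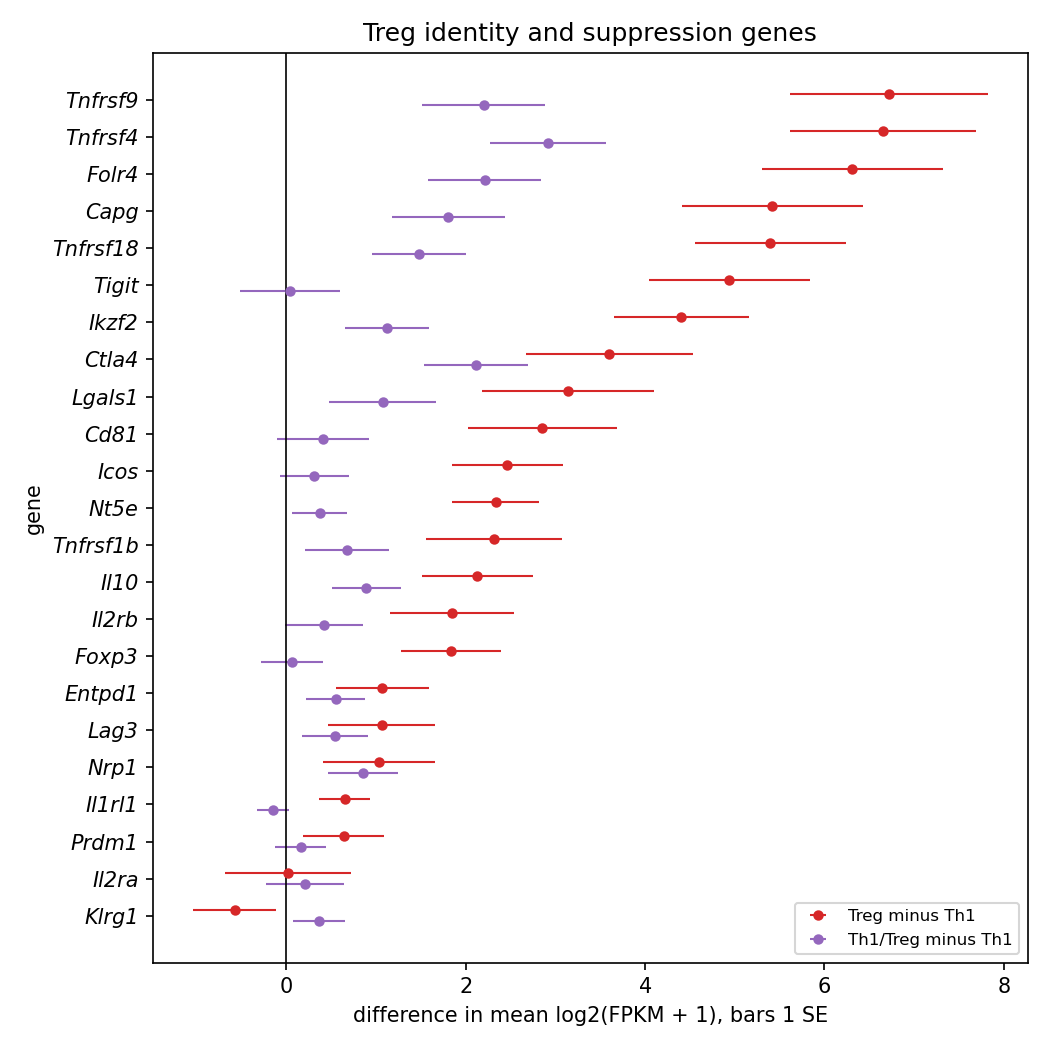
Differences in mean log2(FPKM + 1) of the 23 tested Treg list genes are plotted, Treg minus Th1 in red and Th1/Treg minus Th1 in purple, with bars of 1 SE. Tnfrsf4 lies at 6.65 and 2.92, and Tigit at 4.94 and 0.04.

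Counting genes of the Treg list in each cell, a measure chosen after the data were examined, placed the classes in the same order. The count uses the same list and cells as the list test, so it is no separate support. It was not adjusted for genes detected, with which it can rise. Th1 cells averaged 8.42 list genes at 1503.8 genes detected in chip 5, and 1.75 at 710.1 in chip 6. Genes detected were lower in Th1/Treg than in Treg cells in 4 of 4 chips, but higher in Treg than in Th1 cells in only 2 of 4. In the 4 chips with every class, Treg cells had 12.4 ± 2.03 of the 23 genes above 1 FPKM, Th1/Treg cells 8.03 ± 1.97 and Th1 cells 4.82 ± 2.98 (SD, n = 4 chips). The order Th1, Th1/Treg, Treg held in each of these chips, and the exact sign-flip p was 0.125 for each pair, the smallest possible. Over all 6 chips with Th1 and Th1/Treg cells, Th1/Treg cells had 2.65 ± 1.81 more (SD, n = 6 chips, exact sign-flip p = 0.0625) and were higher in 5 of 6. In chip 2 the order was the opposite, with 4.52 in Th1 and 4.33 in Th1/Treg cells. On the axis of 200 genes, where Th1 is 0 and Treg is 1, Th1/Treg cells lay at 0.235 ± 0.267 (SD, n = 4 chips). The chip values were -0.0948, 0.136, 0.406 and 0.491, and the exact sign-flip p against 0.5 was 0.125, again the smallest possible. The position was 0.143 without chip 7, and 0.490 with the log taken of the mean FPKM (exact sign-flip p = 1), so a place nearer to Th1 cells depends on how cells are averaged.

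**Figure D3:**
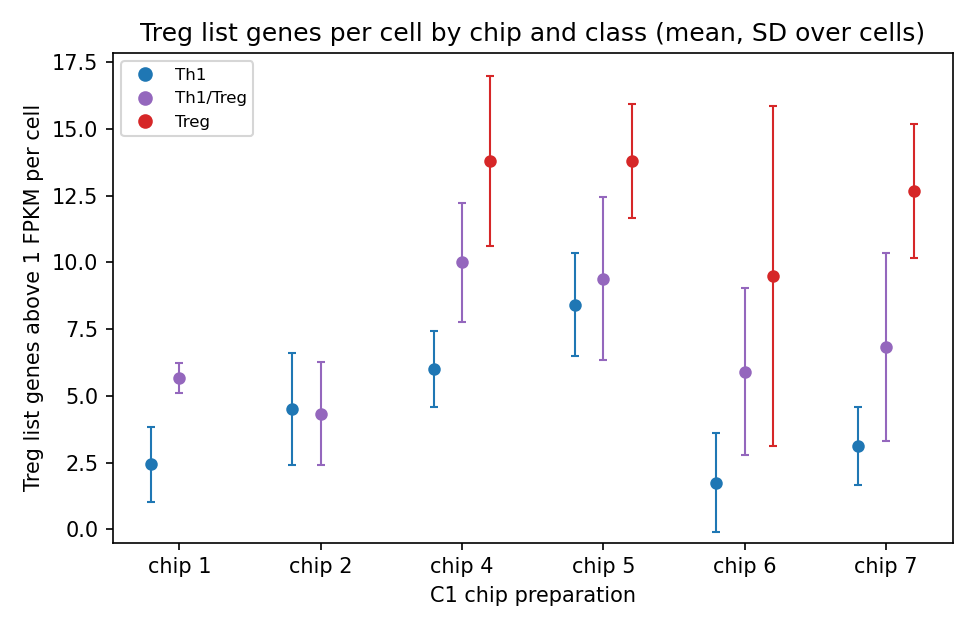
The number of Treg list genes above 1 FPKM per cell is plotted for each chip and class of at least 2 cells, as the mean with a bar of 1 SD over cells. In chips 4, 5, 6 and 7, Treg cells average 12.4 genes, Th1/Treg cells 8.03 and Th1 cells 4.82.

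Joint listing of lineage genes was rare. Foxp3 together with Tbx21 or Ifng was above 1 FPKM in 1 of 71 Th1/Treg cells, 1 of 21 Treg cells and 0 of 81 Th1 cells. Among the Th1/Treg cells, 6 listed Foxp3 without the others and 13 listed Tbx21 or Ifng without Foxp3. With each side listed in so few cells, a low joint count is no evidence against joint expression. Genes detected per cell differed by -43.1 ± 223.1 between Th1/Treg and Th1 cells (SD, n = 6 chips, exact sign-flip p = 0.656) and by 212.2 ± 268.2 between Treg and Th1 cells (SD, n = 4 chips, exact sign-flip p = 0.5).

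The called genes lie on many chromosomes of GRCm38. Tnfrsf9 spans 150914562 to 150946102 on chromosome 4, where Tnfrsf4 (156013843 to 156016612) and Tnfrsf18 (156026164 to 156028895) are neighbours. Tigit spans 43648867 to 43664146 on chromosome 16, Folr4 14885814 to 14903949 on chromosome 9, and Ikzf2 69531214 to 69687245 on chromosome 1. Capg spans 72544391 to 72562983 on chromosome 6, Srgn 62493833 to 62527451 on chromosome 10, and Il2rg 101264378 to 101268255 on chromosome X. All are annotated as protein-coding, and the FPKM values cover the whole gene and not single exons.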

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

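The tests of genes detected, of other-cell RNA, of doublets, of swaps within chips and of the splits for the comparisons with Th1/Treg cells were chosen after the results were seen. Those of the split of Treg and Th1 cells, of a mixture and of receptor genes were written before their results.

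Genes higher in Treg than in Th1 cells were weighed first. Among splits that mix the chips, 1 of 100, the real split, gave a count of 17 or more, and the highest other gave 7. This met the bound set beforehand against chance. Such splits break the pairing of classes within chips, so they do not exclude chance for paired data. Swaps of the classes within chips, which keep the pairing, number 16, too few for a share under 0.05, and the highest other gave 4. A difference in genes detected is argued against as the main source, though for genes chosen in the same data. The median difference of the 17 genes was 4.41 ± 0.84 (SE) and 4.44 ± 0.88 (SE) with that number as a covariate, and 12 stayed past the threshold. Genes detected were higher in Treg cells in 2 of 4 chips. With cells of at least 1000 genes, 4 genes were called. RNA of B cells or myeloid cells may still contribute. Over the cells of all chips together, at least 2 markers of the B cell list or of the myeloid list were above 1 FPKM in 17 of 21 Treg and 34 of 81 Th1 cells. That contrast mixes classes with chips. Within chips, Treg cells had more myeloid markers per cell in 3 of 4 chips and more B cell markers in 2 of 4. With the number of these markers as a covariate the median was 4.24 ± 1.46 (SE), higher in all 17 genes, and 0 passed. The standard error grew, and the median difference of the Treg list fell from 2.33 to 1.89. This source cannot be told apart from a difference between the classes. How the authors classed the cells was not tested and stays open.

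Chance cannot be excluded either for the single genes called in the other comparisons. For Th1/Treg minus Treg, 9 of 100 splits gave at least the real count of 1, with a highest other of 5. For Th1/Treg minus Th1, 14 of 100 splits did so against a real count of 1, with a highest other of 9.

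The number of Treg list genes per Th1/Treg cell lay between those of the other classes in chips 4, 5, 6 and 7. Single members differed, with Tigit and Foxp3 near the Th1 level at 0.04 and 0.06 relative to Th1 cells. A Th1 and a Treg cell caught together in 1 chamber were a candidate explanation. Such a pair should have more genes detected than the mean of Th1 and Treg cells of its chip, and Th1/Treg cells had -92.7 ± 134.2 (SD, n = 4 chips) relative to it, lower in 3 of 4 chips. The spread between chips leaves that measure undecided. Such a pair should also hold the Treg list genes of its Treg cell. Th1/Treg cells differed from Treg cells by -4.41 ± 1.01 of the 23 genes (SD, n = 4 chips) and were higher in 0 of 4 chips. That lower count is part of the pattern itself and no separate test, and it was not adjusted for genes detected. It is not what such pairs should give for the class as a whole, but doublets were not excluded. Pairs among single cells stay possible. A class made of whole Th1-like and Treg-like cells could give middle values. The variance between Th1/Treg cells was 0.549 times that of such a mixture, with a bootstrap 95% interval from 0.349 to 1.09. The bootstrap drew cells within each chip and class, so the interval leaves out the spread between chips. The interval held 1, which met the bound set beforehand in favour of a mixture. That bound was too lax, since a wide interval meets it whatever the class is. A limit on the width was therefore added to the test, and a mixture cannot be told apart from a class of its own. A difference between the classes themselves was not tested against these.

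Receptor genes of the nose stood out in T cells. Olfr856-ps1 was above 1 FPKM in 87.8% of cells, Vmn1r58 in 80.9%, Olfr613 in 80.2% and Vmn2r55 in 25.95%. Reads of another annotated gene at the same position were a candidate explanation. Of these 4 genes, 0 overlap another gene, against 10.2% of 1384 receptor genes above 1 FPKM in under 1% of cells (one-sided Fisher exact p = 1). This met the bound set beforehand against the explanation, and none of the 4 genes has another gene of GENCODE M21 at its position on either strand, which argues against it. Other sources of these reads stay open, and no biological explanation was tested.

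Chip means far from the others were found in 23 groups, 22.3% of those tested, where chance gives about 1 in 20 for normally distributed values. That rate was not measured on these data, and it need not hold where the other chips stand at 0, as for Ifng, Inpp5k, Eif1a and Fam105a in Treg cells. Many lie in the Th1 cells of chip 4, which are 2 cells. There Tigit had a mean log2 value of 7.89, Il2rg 8.56, Folr4 5.98, Bin3 5.44, Pglyrp1 3.48, Foxp3 2.95 and Inpp5k 2.05. Th1 cells of chip 5 stood apart for Tnfrsf9 at 2.74, Tnfrsf4 at 2.48 and Ifng at 1.265, and those of chip 1 for Glrx at 4.06. In Treg cells, chip 4 stood apart for Ifng at 1.93 and Inpp5k at 1.83, chip 6 for Glrx at 7.53 and Vps54 at 4.83, and chip 5 for Fam105a at 0.41 and Eif1a at 0.0795. In Th1/Treg cells, chip 1 stood apart for Ikzf2 at 5.91 and Pydc3 at 2.16, chip 2 for Srrt at 0.99, chip 4 for Fam120b at 1.04, and chip 5 for Fam105a at 0.53 and Cep57 at 0.50.

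In the 88 cells without a class, some genes had shares above the 3.41% that a count of 0 allows, which is no test against the classed cells. Foxp3 was above 1 FPKM in 7.95% of them, Tnfrsf9 in 17.05%, Tigit in 25% and Il2rg in 69.3%. The share of Foxp3 has a Clopper-Pearson 95% interval from 3.26% to 15.7%, which reaches below that limit. Tbx21 and Ifng, at 2.27% each, and Cxcr3, at 3.41%, were not above it. In classed cells the shares were 11.6% for Foxp3, 43.9% for Tnfrsf9, 51.4% for Tigit and 74.6% for Il2rg.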

How the results depend on the processing

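The covariate of other-cell markers, the approximate standard errors, the misplaced column kept, the near-identical pair as 2 cells and the short genes left out were chosen after the data were seen. The approximate standard errors were those of the first fit, replaced after its calls had been seen. The 12 named genes higher in Treg than in Th1 cells stayed higher under every alternative that tested them, Tigit stayed lower in Th1/Treg than in Treg cells, and Il2rg stayed higher in Th1/Treg than in Th1 cells. These genes were chosen in the same data, most of them for the same direction in every chip, so a kept direction is weak evidence. The Treg list kept its direction in each comparison. Past the threshold, the results were less stable. Of the values that answer a comparison, 98 were the same under an alternative, 67 moved, 26 were weaker and 1 reversed. Of those of single genes, 190 were the same, the rest were weaker and none reversed. Read depth is unknown, which limits what a value of 0 means. Where no cause is given, the cause was not tested.

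Against 1 gene called for Th1/Treg minus Treg, 1 for Th1/Treg minus Th1 and 17 for Treg minus Th1, the counts in that order were as follows. Without a filter on low values they were 0, 0 and 0, over 14199 genes. With a filter at 25% of cells they were 3, 1 and 11, over 1106 genes. With log2 of the mean FPKM they were 0, 2 and 1. With genes detected as a covariate they were 0, 0 and 12, with cells of at least 1000 genes 0, 0 and 4, and with the other-cell markers as a covariate 0, 1 and 0. With at least 4 cells per chip and class they were 0, 1 and 0, and with the approximate standard errors 0, 0 and 10. Each cell scaled to the same sum gave 4, 1 and 18, equal weights 1, 0 and 20, and a pseudocount of 0.1 gave 0, 1 and 17. Without cells holding 2 or more B cell or myeloid markers and without the 5% of cells with the most genes, 91 cells in all, the count for Th1/Treg minus Th1 was 0, and the comparisons with Treg cells could not be run because no chip kept 2 Treg cells.

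With each chip left out in turn, the counts ran from 0 to 7, from 0 to 2 and from 0 to 18. The lists called ran from 0 to 1 for both comparisons with Th1/Treg cells and from 0 to 2 for Treg minus Th1. The adjusted p of the Treg list ran from 0.00446 to 0.227 for Th1/Treg minus Treg, from 0.0061 to 0.21 for Th1/Treg minus Th1 and from 0.000677 to 0.0657 for Treg minus Th1, the last without chip 5. That of the naive and central memory list ran from 0.0401 to 0.116.

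The chip as a block changed calls. Without it, the counts were 0, 1 and 76, and 1 list was called for Treg minus Th1, where the naive and central memory list had an adjusted p of 0.0756.

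For lists, 1, 1 and 2 were called. A preset correlation of 0.01 gave 5, 3 and 4, and fry, which does not compare a list with other genes, gave 8, 1 and 10. With log2 of the mean FPKM, 0, 0 and 2 were called. The Treg list then had an adjusted p of 0.55 for Th1/Treg minus Treg and 0.155 for Th1/Treg minus Th1, and the naive list 0.0899. With genes detected as a covariate, 0, 0 and 3 were called, and the Treg list had 0.0722 and 0.269. With each cell scaled to the same sum, 0, 0 and 2 were called, and the Treg list had 0.0509 and 0.0603. With the other-cell markers as a covariate, 0, 1 and 0 were called, and the Treg list had 0.469 for Th1/Treg minus Treg and 0.115 for Treg minus Th1, and the naive list 0.217.

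Genes detected per cell reversed for Th1/Treg minus Th1 at FPKM above 10, to 15.7. The position of Th1/Treg cells ran from 0.143 to 0.490 over its alternatives.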

Other observations

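The gene lists were fixed before the data were examined, while the marker counts by chip and the Treg shares by chip were chosen after they were seen, and no explanation was tested here.

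Other gene groups were tested in the same way, and sizes of change were not compared between lists. The median difference of all 3381 tested genes was 0.20 for Treg minus Th1. A majority of members higher is therefore no sign of a change particular to a list. In Treg minus Th1, activation and costimulation had 14 of 17 members higher and co-inhibition 7 of 8, with a camera adjusted p of 0.0835 each. T cell receptor genes were higher in 18 of 24, dissociation stress in 18 of 24, interferon response in 17 of 23, and STAT5 and interleukin 2 in 10 of 12. Myeloid markers were higher in 4 of 5 and B cell markers in 4 of 5, Tfh genes in 5 of 7, TGF-beta in 5 of 7, and PI3K with AKT, mTOR and FOXO in 9 of 12. Apoptosis genes were higher in 8 of 11, cytotoxic granule genes in 5 of 7, oxidative phosphorylation in 32 of 40, glycolysis in 11 of 12, cholesterol and lipid handling in 5 of 7, chemokine receptors and adhesion in 10 of 15, and cell cycle in 7 of 11. The adjusted p of the lists from T cell receptor to cell cycle ran from 0.360 to 0.952. Of the lists too small for the test, Th17 had 2 of 2 members higher, Th2 3 of 3, sort gate 3 of 3, CD8 T and NK 1 of 3, and red cell genes 1 of 2.

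In the comparisons with Th1/Treg cells, the other 20 lists had an adjusted p from 0.153 to 0.962 against Treg cells and from 0.193 to 0.858 against Th1 cells. Against Th1 cells, the naive and central memory list had 14 of 15 members lower, and Lef1, a transcription factor of naive T cells, passed over the list alone at -1.83 ± 0.56 (SE), lower in 5 of 6 chips. A preset correlation of 0.01 also called the activation list in all 3 comparisons, the co-inhibition list in Treg minus Th1, the naive list in both comparisons with Th1/Treg cells, and the oxidative phosphorylation and myeloid lists in Th1/Treg minus Treg. None of these calls held with the estimated correlation.

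Some transcripts of the B cell and myeloid lists were common in some chips of sorted T cells. Of all classed cells, Cd74, the invariant chain, was above 1 FPKM in 57 and the B cell receptor gene Cd79a in 34. The B cell genes Cd19 and Ms4a1 were above it in 0. Of the myeloid list, Ctss, a protease of antigen-presenting cells, was above it in 59, Fcer1g in 48 and Cst3 in 34. Other myeloid genes were rare, with Cd68 in 4, Lyz2 in 3, Csf1r in 3 and S100a8 in 0. At least 2 B cell markers were above 1 FPKM in 42 of 50 cells of chip 5 and 9 of 12 of chip 4, but in 0 of 29 of chip 6.

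The share of Treg cells differed between chips. It was 0 of 10, 1 of 40, 5 of 12, 10 of 50, 2 of 29 and 3 of 32 classed cells in chips 1, 2, 4, 5, 6 and 7. The median genes detected in these chips were 685, 643, 1308.5, 1375, 733 and 1205. The chips form separate clusters on that measure, from 643 to 733 and from 1205 to 1375, and no correlation is given across them or within clusters of 3 chips.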
